A study of Mus musculus with 14 samples.

How the data were processed

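Gene expression was measured with 14 Agilent 1-colour mouse arrays in CD4-CD8- thymic cells of C57BL/6 background. Lethally irradiated CD45.1+ mice had received bone marrow that carried a tamoxifen-dependent Cre alone (WT), with floxed Ezh2, with floxed p53 (the gene Trp53), or with both. Per the labels, deletion followed 4 weeks after transplantation, and the non-leukemic cells were sorted 3 months after transplantation. The labels give no such time for the leukemic cells. The 12 non-leukemic arrays hold 1 array for each of 4 genotypes and 3 stages: DN1 (CD44+CD25-), DN2 (CD44+CD25+) and DN3 (CD44-CD25+). The other 2 arrays hold leukemic cells, sorted by the DN2 gate, from 2 double-deleted mice with early T cell precursor leukemia (ETP-ALL). The treatment text of the labels speaks of sorted bone marrow cells, while the series design and the sample labels speak of the thymus; the latter were followed here.

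Per the labels' protocols, RNA was extracted with a silica column kit and 20 ng of total RNA, with spike-in controls, was amplified and labelled with Cy3. Per the file headers, the authors scanned the arrays with an Agilent scanner and read them with Feature Extraction 10.7.1.1, which made the deposited signal intensity of each spot by background subtraction and spatial detrending, with dim spots set to a small positive surrogate and no scaling between arrays. The deposited scanner files also give the raw median intensity of each spot and of its local background, and flags for spots well above background, saturated or outlying. How the authors normalised their deposited value table is not given in the sources used here. Each of its signal columns matched the processed intensity of its array divided by 1 constant, with a 75th percentile between 1.002 and 1.004 and a column median between 0.065 and 0.105, so it is linear, uncentred and scaled per array. The build of the array grid (mm9) differs from that of the reference table (GRCm38.p6), so no coordinates are printed.

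Here, log2 of the processed intensity minus the 75th percentile of its array was used. Control spots and spots marked as outliers were left out, and spots of 1 probe were averaged, which took 59305 spots to 55681 probes. A RefSeq accession matched to the GRCm38.p6 gene table gave 27656 probes 1 gene symbol and none several. The other 28025 probes were tested under their probe names and are not named here. A probe was tested if it was well above background on at least 2 of the 14 arrays, and a gene was represented by its probe with the highest mean, which gave 27067 features, 14254 of them named genes. Where 2 probes of a gene moved in opposite directions by over 0.5, this is said.

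Between 40.3% and 50.4% of probes were well above background on each array, and no probe was saturated. For a gene that was not well above background on any array of a group only a bound is given, "at least N-fold". It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of 2 values: the lowest signal among probes well above background on that array and the probe's own signal.

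Genotype and stage were fitted as additive terms to the 12 non-leukemic arrays with limma 3.58.1 (lmFit and eBayes, with Benjamini-Hochberg adjustment over the features of each comparison) in R 4.3.3, and genes with an adjusted p under 0.05 were called. This left 6 residual degrees of freedom, with 2.86 added by the empirical Bayes prior. The 2 leukemic arrays were set against the additive estimate for double-deleted DN2 cells in a fit of all 14 arrays, with 7 residual degrees of freedom. Every p is an adjusted p of limma unless stated. The labels do not say that the stages of a genotype came from separate mice, so a p between genotypes measures agreement over 3 stages and not the spread between mice. The number of arrays limits the precision of all values.

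There were 9 comparisons and 22 gene lists: p53 target genes, PRC2 components, canonical PRC2 target genes, T-lineage transcription factors, pre-TCR and TCR signalling genes, Notch target genes, stem and early progenitor genes, myeloid genes, B-lineage genes, antigen presentation and dendritic cell genes, NK and innate lymphoid genes, gamma delta T genes, double-positive thymocyte genes, erythroid and megakaryocyte genes, thymic stroma and endothelium genes, cell cycle genes, MYC and ribosome biogenesis genes, IL-7 receptor and JAK-STAT genes, DNA methylation genes, interferon response genes, immediate-early and heat-shock genes, and apoptosis regulators of the BCL2 family. The lists, groups, comparisons and naming rule were fixed before the data were examined, as were the tests and other settings not named as later additions. Each list was tested in each comparison with limma's camera at a preset correlation of 0.01, and Benjamini-Hochberg adjustment ran over the 198 tests. Of these, 56 were called, and with an estimated correlation 0 were called; that second p stands beside each list. Differences between single arrays carry no test, and the median of a list was there set against 10000 random lists of its size matched on mean expression.

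The rule for named genes took Ezh2 and Trp53, the 8 genes that rose and the 8 that fell most among those called with 1 direction in every genotype, stage or leukemia, up to 4 members of each list by smallest p, and a fixed set of T-lineage and p53 pathway genes. Of the genes this rule allows, the text names part, chosen after their values were seen, so the direction shared by these genes over genotypes, stages or leukemias is partly set by the rule; for the 4 comparisons confounded with slide the selection is smaller.

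The arrays came from 4 slides, each scanned in a session of its own over 3 years. Slide 1 held the 3 WT arrays and double-deleted DN2 and DN3. Slide 2 held all Ezh2-deleted and p53-deleted arrays, slide 3 held double-deleted DN1, and slide 4 held both leukemic arrays. The slide was added as a fixed block, or as a random block (statmod 1.5.0) where a comparison lies wholly between slides. Double-deleted against WT was fitted with each kind of block. Comparisons were rerun within a slide where they could be. In such a fit of slide 1, WT DN1 is the only DN1 array and 1 residual degree of freedom is left. Other alternatives were normexp on the median spot and background intensity with an offset of 50, quantile normalization, no filter or a strict filter on dim probes, the mean of all probes of a gene, the authors' value table, a trended and robust prior, and leaving out each array in turn. The 75th percentile over probes detected on all arrays, a filter on detection throughout 1 group, and the fits within or without a slide (except that of double-deleted and WT arrays on slide 1) were added after seeing the data.

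Each comparison was tested on simulated data with 200 of 26993 features changed. For changes of 1 on the log2 scale, 0% were called in each of the 9 comparisons. For changes of 2, the share called was 66% for DN2 against DN1, 63.5% for DN3 against DN2, 48% for double-deleted against WT, 56.5% for Ezh2-deleted against p53-deleted, 23% for the interaction and 32.5% for ETP-ALL, so smaller changes could be missed. Where many more features change than the 200 simulated, the adjusted threshold is less strict. These shares therefore do not carry over to comparisons with many calls, where some changes near 1 were called.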

Results

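Expression was profiled at 3 early stages of T cell development in the thymus of recipients of WT, Ezh2-deleted, p53-deleted and double-deleted bone marrow, and in 2 leukemias that arose in double-deleted recipients. Ezh2 is the methyltransferase of Polycomb repressive complex 2 (PRC2), which silences developmental genes, and p53 is a tumour suppressor that arrests or kills damaged cells. Each genotype and stage had 1 array, so a genotype was represented by 3 arrays and a stage by 4. The 75th percentile of the processed signal lay between 70.5 and 141 on the 6 arrays of slide 2 and between 299 and 589 on the other 8. The first principal component of the 12 non-leukemic arrays held 38.2% of the variance and placed the slide 2 arrays, at 45.4 to 136, apart from the rest, at -129 to -39.8. The highest correlation between 2 of these arrays was 0.983. Across all features, arrays of different genotypes had a median correlation of 0.946 over 15 pairs on the same slide. It was 0.900 over 39 pairs on different slides, most of which also set Ezh2-deleted or p53-deleted cells against WT or double-deleted cells. For arrays of the same genotype it was 0.9575 over 10 pairs on the same slide and 0.9545 over 2 pairs on different slides. Features are not independent replicates, so these correlations describe the arrays alone.

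The targeted genes were examined first on every array. The probe of Trp53 was not well above background in p53-deleted DN1, DN2 and DN3 cells, at log2 values of -3.7, -5.58 and -5.05. In WT cells of the same stages it stood at -0.02, 0.87 and 1.12. Only bounds are given for this fall, with the comparisons below. In double-deleted DN1, DN2 and DN3 cells Trp53 stood at 6.08%, 9.09% and 21.5% of the WT level of the same stage. In 1 leukemia it was not well above background, and in the other it stood at 3.33% of WT DN2. Ezh2-deleted cells had 138%, 153% and 95.3%. The probe of Ezh2 itself read 125%, 80.7% and 60.3% of WT in Ezh2-deleted cells, and 269%, 109% and 74.2% in double-deleted cells. Where this probe lies relative to the deleted part of Ezh2 is not given in the sources used here, so it checks no label. Ezh2 passed the test in none of the 9 comparisons under limma. Cdkn2a, which encodes the tumour suppressors p16 and p19 and is silenced by PRC2, stood at log2 values of -3.17, -5.44 and -3.61 in WT cells, the latter 2 not above background. It reached 0.87 to 2.54 in Ezh2-deleted, 6.18 to 6.41 in p53-deleted and 4.60 to 5.29 in double-deleted cells, and 6.53 and 7.06 in the leukemias. Xist, the RNA that silences an X chromosome in female cells, was well above background on the 3 Ezh2-deleted arrays alone, at 1.54 to 2.37. The Y-linked genes Ddx3y, Eif2s3y and Uty were below background on those 3 arrays and above it on all others. The labels give no sex, and each comparison with Ezh2-deleted cells also sets these arrays against arrays with Y-linked transcripts.

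**Figure D1:**
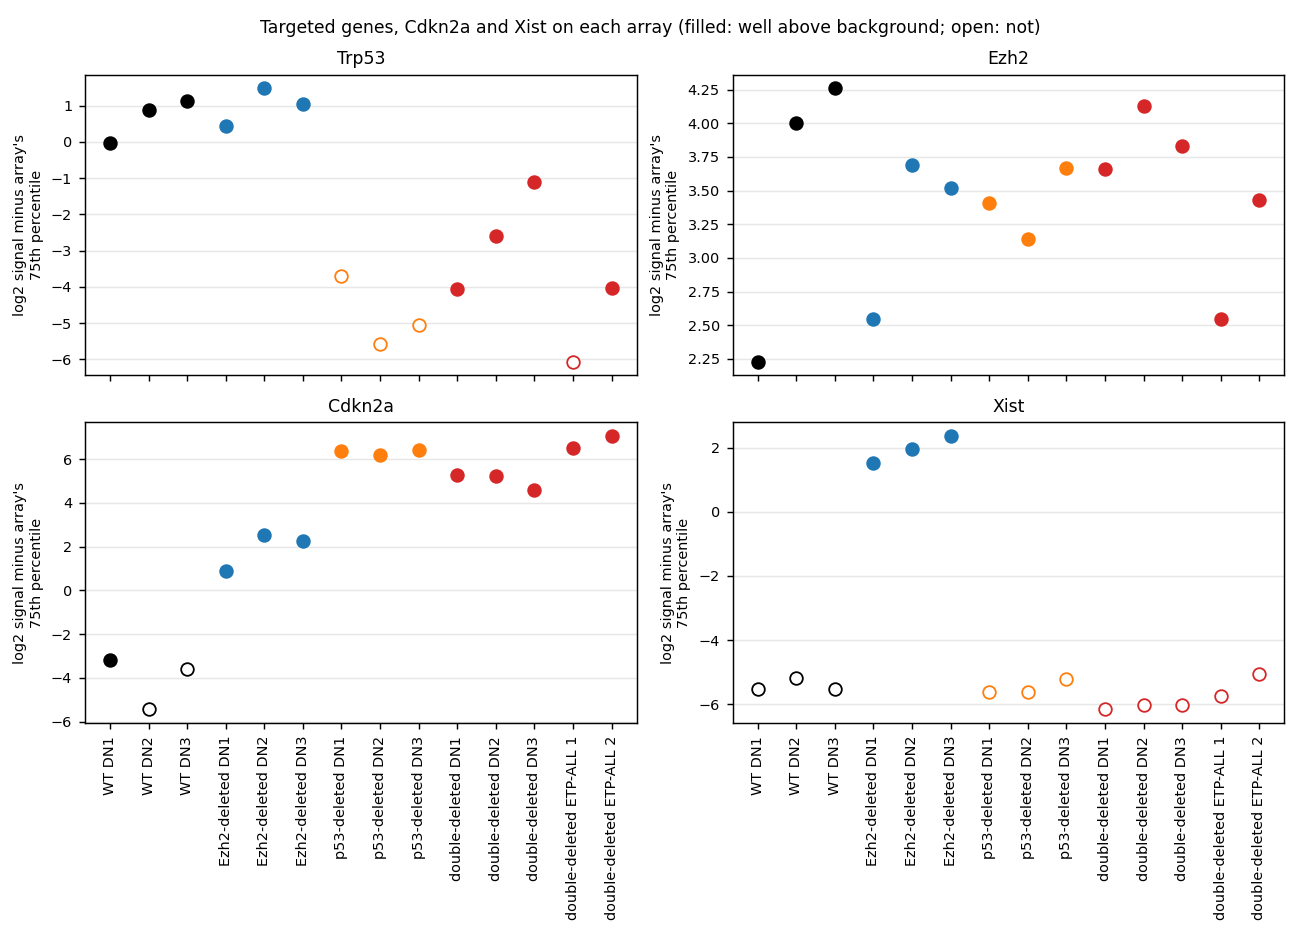
Levels of Trp53, Ezh2, Cdkn2a and Xist on each of the 14 arrays, as log2 signal minus the 75th percentile of its array; filled points are well above background and open points are not. Trp53 is lowest on the p53-deleted, double-deleted and leukemic arrays, Cdkn2a is highest on the same arrays, and Xist is above background on the 3 Ezh2-deleted arrays alone.

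Between DN1 and DN2, genes of natural killer (NK) cells fell by the most. The stages were gated on CD44 and CD25. Lower expression within cells and a different mix of sorted cells therefore cannot be told apart, for this or any list of this step. Klra4 and Klra9, NK receptors of the Ly49 family, were at least 135-fold and at least 199-fold lower in DN2 cells, where they were not above background. Klra8 fell by 7.76 ± 1.03 on the log2 scale (SE, 4 arrays per stage, adjusted p = 0.00833), Klra7 fell by 7.72 ± 0.56, and Klra16 fell by 7.03 ± 0.69. Klrd1, a subunit of NK receptors, fell by 7.18 ± 0.65, and Klre1 fell by 6.47 ± 0.56. Eomes, a transcription factor of NK and memory T cells, fell by 5.61 ± 0.82, and Il2rb, the beta chain of the IL-2 and IL-15 receptors, fell by 5.21 ± 1.02. In DN2 cells Klra7, Klrd1 and Klre1 were above background on 1 of 4 arrays, Klra8 and Eomes on 2 of 4 and Klra16 on 3 of 4. Of the 33 NK and innate lymphoid genes, 12 fell and none rose over all genes tested, and 26 fell adjusted over the list alone, with a list median of -3.09 (camera adjusted p = 5.47e-26, and adjusted p = 0.589 with an estimated correlation). The NK median was -2.77 with slide as a block and -2.74 within slide 2. Slide 1 holds 1 DN1 array, of WT cells, so for DN1 it gives no replicated test. On single arrays the list stood at 3.37, 3.11, 2.01 and 1.16 in WT, Ezh2-deleted, p53-deleted and double-deleted DN1 cells, and at -2.43, -0.23, 0.57 and -2.58 in DN2 cells.

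Genes of B and myeloid cells were also lower in DN2 than in DN1 cells. Ms4a1, which encodes the B cell surface protein CD20, was at least 28.3-fold lower, and Fcmr, a receptor for IgM, fell by 4.07 ± 0.78. Jchain, which joins IgM and IgA into polymers, fell by 6.87 ± 0.62 (adjusted p = 0.00142), and Slpi, a secreted protease inhibitor, fell by 7.58 ± 1.20. Slpi was above background on 2 of 4 and Fcmr on 3 of 4 DN2 arrays. Ms4a1 and Fcmr were among the 3 of 20 B-lineage genes called, and 10 fell adjusted over the list alone. The list median was -1.43, or -1.02 with members below background set to their bounds (adjusted p = 3.48e-07, and adjusted p = 0.616 with an estimated correlation). Ms4a3 and Prtn3, of granulocyte precursors, were at least 13.3-fold and at least 8.08-fold lower, each above background on 3 of 4 DN1 arrays. They were the 2 of 32 myeloid genes that fell (3 adjusted over the list alone; median -0.79, adjusted p = 1.02e-07, and adjusted p = 0.616 with an estimated correlation). None of 20 antigen presentation and dendritic cell genes was called, and 4 fell adjusted over the list alone (median -0.77, adjusted p = 0.00403, and adjusted p = 0.799 with an estimated correlation). That median was -0.17 within slide 2, where the list was not called (adjusted p = 0.107).

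T cell and interferon genes fell as well. The co-receptor genes Cd28, Cd6 and Cd5 fell by 1.53 ± 0.20, 1.80 ± 0.27 and 1.81 ± 0.28. Prkcq, a kinase downstream of the T cell receptor, fell by 1.64 ± 0.29, and Cd8b1, a chain of CD8, fell by 1.66 ± 0.32. They were the 5 of 34 pre-TCR and TCR signalling genes that were called, and 15 fell and 3 rose adjusted over the list alone (median -0.40, adjusted p = 5.17e-05, and adjusted p = 0.652 with an estimated correlation). Ifit3, Oas3, Ifit1 and Irf7, all induced by interferon, fell by 3.43 ± 0.45, 1.63 ± 0.22, 1.47 ± 0.26 and 1.46 ± 0.27. Ifit3 and Cd8b1 were above background on 3 of 4 DN2 arrays. Of 28 interferon response genes these 4 were called, and 15 fell and 1 rose adjusted over the list alone (median -0.70, adjusted p = 1.29e-11, and adjusted p = 0.589 with an estimated correlation). Itm2a, a thymocyte surface protein, fell by 1.83 ± 0.31, and with Cd8b1 made up the 2 of 22 double-positive thymocyte genes that fell, with 5 falling and 1 rising adjusted over the list alone (median -0.86, adjusted p = 0.000283, and adjusted p = 0.634 with an estimated correlation). Cd28 was the 1 called of 14 gamma delta T genes, of which 3 fell adjusted over the list alone (median -1.42, adjusted p = 3.63e-06, and adjusted p = 0.706 with an estimated correlation). The gamma delta median was -0.56 within slide 2, where it was not called (adjusted p = 0.188).

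The gene that rose most from DN1 to DN2 was Il2ra, which encodes CD25, the protein that the sort gate itself selects, by 5.08 ± 0.37 (adjusted p = 0.000528). Myl10, a myosin light chain, rose by 3.49 ± 0.67, Acot5, a peroxisomal thioesterase, by 3.23 ± 0.60, the kinase Dyrk4 by 3.18 ± 0.44, and Smim5 by 2.92 ± 0.50. The ephrin receptor Epha2 rose by 3.17 ± 0.54 and was above background on 3 of 4 DN2 and 1 of 4 DN1 arrays. Mc1r, the melanocortin receptor, was at least 7.5-fold and Cldn2, a tight junction protein, at least 3.6-fold higher, Cldn2 on 3 of 4 DN2 arrays. Notch3, a receptor and target of Notch signalling, rose by 2.23 ± 0.41. Il2ra and Notch3 were the 2 of 15 Notch target genes that rose, and adjusted over the list alone 7 rose and 1 fell (median 0.82, adjusted p = 0.000231, and adjusted p = 0.589 with an estimated correlation). None of 39 cell cycle genes was called over all genes by limma, yet 33 rose adjusted over the list alone (median 1.18, adjusted p = 1.29e-11, and adjusted p = 0.788 with an estimated correlation). Its median was 0.78 within slide 2. No MYC and ribosome biogenesis gene was called either way (median 0.62 over 30, adjusted p = 1.78e-06, and adjusted p = 0.825 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 2.71 ± 0.28 (adjusted p = 0.00235), and Hoxa7, a homeobox gene, by 1.67 ± 0.31. Dyrk4 and Hoxa7 were above background on 3 of 4 DN1 arrays, and Smim5 on 3 of 4 arrays of each stage. Notch1 (1.38 ± 0.33, adjusted p = 0.0931), Runx1 (0.73 ± 0.26) and Lef1 (-1.39 ± 0.56), transcription regulators of early T cells, did not pass the test, nor did Ezh2 (0.77 ± 0.34) or Trp53 (0.38 ± 0.61).

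In all, 373 features differed between DN1 and DN2 (45 rose, 328 fell, of which 35 and 131 were named genes), against 5297 at an unadjusted p under 0.05 and a median change of all features of 0.13. The lists of T-lineage transcription factors (median -0.45, adjusted p = 0.0247, and adjusted p = 0.799 with an estimated correlation), IL-7 receptor and JAK-STAT genes (median -0.34, adjusted p = 0.0132, and adjusted p = 0.825 with an estimated correlation) and immediate-early and heat-shock genes (median -0.54, adjusted p = 0.0376, and adjusted p = 0.885 with an estimated correlation) were also called as lower. None of these 3 was called within slide 2 alone, and with slide as a block the first (-0.44, adjusted p = 0.102) and the last (-0.58, adjusted p = 0.0679) were not. Of the 14 lists called, 8 moved against the called direction in p53-deleted cells. There gamma delta T genes went from 0.36 at DN1 to 2.11 at DN2, immediate-early and heat-shock genes from 4.55 to 5.84, IL-7 receptor and JAK-STAT genes from 2.47 to 3.45, antigen presentation and dendritic cell genes from 0.99 to 1.48, double-positive thymocyte genes from 2.52 to 2.87 and T-lineage transcription factors from 3.91 to 4.08. Cell cycle genes went from 3.72 to 3.51 and MYC and ribosome biogenesis genes from 3.59 to 3.42. The block amounts here to leaving out double-deleted DN1, the only array of slide 3. It called 317 features, the changes of the 36 called genes named above were 0.884 to 1.19 times as large, and 26 kept their call, while Cd5, Cd6, Cd8b1, Cldn2, Epha2, Ifit1, Il2rb, Itm2a, Prkcq and Prtn3 did not. Within slide 2 the count was 5, and 3 of the 36 genes kept their call, with changes 0.627 to 1.23 times as large. Without slide 2, 11 of the 36 did, with changes 0.769 to 1.37 times as large. Within slide 1, with WT DN1 as the only DN1 array, the changes were 0.723 to 1.62 times as large. Leaving out 1 array moved the count of features from 141, without Ezh2-deleted DN2, to 2418, without p53-deleted DN1. The balance moved too, to 1289 higher and 1129 lower without that array and to 603 and 1187 without p53-deleted DN2.

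Fewer genes separated DN3 from DN2 cells. Il34, a ligand of the CSF1 receptor, rose by 3.06 ± 0.28 (4 arrays per stage, adjusted p = 0.0117). Clnk, an immune cell adaptor, was at least 14.5-fold lower (adjusted p = 0.0117), Napsa, an aspartic protease, at least 17.1-fold lower (adjusted p = 0.0430) and Cela1, an elastase, at least 2.54-fold lower (adjusted p = 0.0431). These 4 and 2 features with no gene name were all that passed, out of 1716 at an unadjusted p under 0.05. Cd44, the protein that the gate selects against at DN3, stood at -3.38 ± 0.60 and missed the threshold (adjusted p = 0.158), as did Ezh2 (0.08 ± 0.34) and Trp53 (0.46 ± 0.61).

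No member of any list was called between DN3 and DN2 over all genes, while 10 lists were called as groups. NK and innate lymphoid genes were again lower, 10 of 33 adjusted over the list alone (median -1.28, or -0.69 at bounds, adjusted p = 3.38e-13, and adjusted p = 0.595 with an estimated correlation). Stem and early progenitor genes (median -0.55, 3 of 29 lower adjusted over the list alone, adjusted p = 1.24e-08, and adjusted p = 0.616 with an estimated correlation) and antigen presentation and dendritic cell genes (median -1.01, or -0.59 at bounds, 1 lower, adjusted p = 4.42e-07, and adjusted p = 0.616 with an estimated correlation) went the same way. Erythroid and megakaryocyte genes had 6 of 17 lower adjusted over the list alone (median -0.18, mean -1.38, adjusted p = 0.000237, and adjusted p = 0.589 with an estimated correlation), and myeloid genes 4 of 32 (median -0.30, or -0.15 at bounds, adjusted p = 0.000232, and adjusted p = 0.706 with an estimated correlation). IL-7 receptor and JAK-STAT genes had none (median -0.40, adjusted p = 5.17e-05, and adjusted p = 0.652 with an estimated correlation). Double-positive thymocyte genes were higher, 2 of 22 adjusted over the list alone (median 0.33, adjusted p = 0.0008, and adjusted p = 0.652 with an estimated correlation), and MYC and ribosome biogenesis genes had a median of 0.32 (adjusted p = 0.000784, and adjusted p = 0.885 with an estimated correlation). The medians of gamma delta T genes (-1.06, adjusted p = 0.00755, and adjusted p = 0.872 with an estimated correlation) and interferon response genes (-0.20, adjusted p = 0.00431, and adjusted p = 0.730 with an estimated correlation) were negative. Within slides 1 and 2 the NK medians were -0.58 and -1.95 and the antigen presentation medians -0.17 and -1.80. Within slide 1 the medians of IL-7 receptor and JAK-STAT genes (-0.03, adjusted p = 0.474), gamma delta T genes (-0.04, adjusted p = 0.343) and interferon response genes (-0.005, adjusted p = 0.892) were not called, against -0.69, -1.86 and -0.34 within slide 2. Double-positive thymocyte genes (0.20, adjusted p = 0.366) and MYC and ribosome biogenesis genes (0.24, adjusted p = 0.345) were not called within slide 2. Single genotypes went against these directions, for example with levels at DN2 and DN3 of -1.23 and -0.49 for gamma delta T genes in WT, 2.87 and 2.50 for double-positive thymocyte genes in p53-deleted, and 0.88 and 1.11 for interferon response genes in double-deleted cells. With slide as a block the changes were the same, 4 features were called, and Il34 and Clnk kept their call. Within slide 1 limma called 0 of 1560 at an unadjusted p under 0.05, and within slide 2 it called 0 of 1504. Scaling on probes detected on all arrays called 2 higher and 3 lower in place of 1 and 5.

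**Figure D2:**
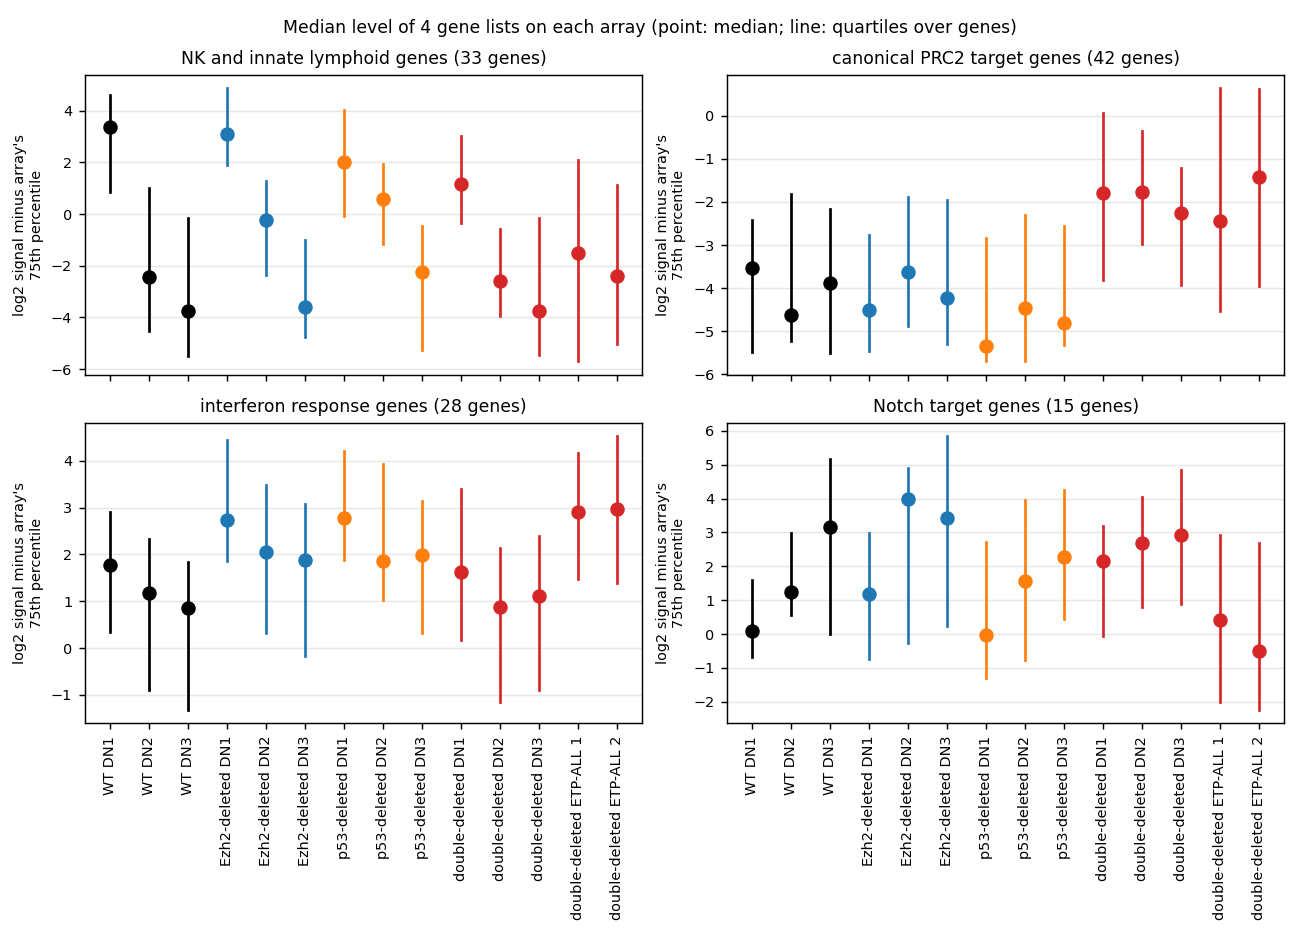
Levels of 4 gene lists on each of the 14 arrays, as log2 signal minus the 75th percentile of its array; points are medians and lines span the quartiles over the genes of the list. NK and innate lymphoid genes decline from DN1 to DN3 in every genotype, canonical PRC2 target genes stand highest on the double-deleted and leukemic arrays, and interferon response genes stand highest on the leukemic arrays, with the slide 2 arrays above those of WT.

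Double-deleted cells were set against WT cells to find what the loss of both genes changes before leukemia. The genes that rose most were Bex1, of a family of small brain-expressed proteins, by 9.31 ± 0.52 (SE, 3 arrays per genotype, adjusted p = 9.23e-05) and Cdkn2a, by 9.12 ± 0.62 (adjusted p = 0.000195), which was above background on 1 of 3 WT arrays. Bex4 was at least 202-fold and Ncam1, the neural adhesion molecule CD56, at least 147-fold higher. Trnp1, a nuclear regulator of neural progenitors, rose by 7.63 ± 0.51 and the sulfatase Arsi by 7.08 ± 0.71, above background on 2 of 3 and 1 of 3 WT arrays. Tenm4, a teneurin whose probes disagreed in sign, was at least 61.6-fold and the synaptic protein Amph at least 55.4-fold higher. Trp53 fell by 3.24 ± 0.70 (adjusted p = 0.0317), Tmem88, a membrane inhibitor of Wnt signalling, by 3.76 ± 0.47, and Rhox2h, above background on 1 of 3 double-deleted arrays, fell by 3.34 ± 0.80. Slc38a8, Olfr56, Cst8 and Kcnh6 were at least 7.65-, 6.48-, 6.15- and 5.41-fold lower, each above background on 2 of 3 WT arrays. Ezh2 did not pass (0.38 ± 0.39).

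Genes that PRC2 is known to silence rose as a group. Of 94 canonical PRC2 target genes, 42 passed the filter on signal. Double-deleted or leukemic arrays alone can satisfy it, so it can favour genes raised there wherever this list is tested or set against random lists. Of these 42, 15 rose and 2 fell over all genes (19 and 6 adjusted over the list alone). Those that rose included Cdkn2a, Lin28b, a fetal RNA-binding protein (at least 12.7-fold higher), and Cdkn1c, a cell cycle inhibitor (3.21 ± 0.23). Cdkn2a stood higher in p53-deleted cells (6.18 to 6.41), though on another slide, than in double-deleted cells (4.60 to 5.29). Its rise is thus not particular to the loss of Ezh2. The list median was 0.94 (camera adjusted p = 8.3e-08, and adjusted p = 0.589 with an estimated correlation), or 0.25 with the 15 members below background in 1 genotype set to their bounds. It was 1.20 with slide as a block and 1.38 for DN2 and DN3 within slide 1. In single arrays the median difference was 0.93, 1.44 and 0.39 at DN1, DN2 and DN3, above at least 99.99% of 10000 matched random lists at each stage. Of the PRC2 components 1 of 11 rose, Phf19, by 1.29 ± 0.31 (median 0.09, adjusted p = 0.336).

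Hey1, a Notch effector, rose by 3.80 ± 0.43 and Igf1r, a growth factor receptor, by 2.19 ± 0.34, the 2 of 15 Notch target genes that rose (3 adjusted over the list alone; median 0.61, adjusted p = 0.00762, and adjusted p = 0.616 with an estimated correlation). No cell cycle gene was called by either adjustment (median 0.69 over 39, adjusted p = 1.93e-05, and adjusted p = 0.885 with an estimated correlation). At DN1, DN2 and DN3 the median differences of that list were 1.92, 0.43 and -0.23, and within slide 1 the list was no longer called (0.12, adjusted p = 0.116). Perp, a p53-induced membrane protein, rose by 3.44 ± 0.62, the 1 of 34 p53 target genes called (median 0.23, adjusted p = 0.0115, and adjusted p = 0.616 with an estimated correlation). With slide as a block the p53 list was not called (adjusted p = 0.0564). Bmf and Bik, which promote cell death, rose by 2.61 ± 0.46 and 3.01 ± 0.74 among 15 apoptosis regulators of the BCL2 family (median 0.11, adjusted p = 0.0987). Dnmt3a, a DNA methyltransferase, rose by 1.21 ± 0.23, and 1 other of 18 DNA methylation genes fell (median 0.27, adjusted p = 0.104). Bmi1, of Polycomb complex 1, rose by 1.80 ± 0.29 and Socs2, a brake on cytokine signals, by 3.34 ± 0.49. Perp was above background on 2 of 3 and Bik on 1 of 3 WT arrays.

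Genes of other cell types moved in both directions in double-deleted cells. Of 32 myeloid genes 3 rose and 1 fell, and the median (-0.58) and mean (0.05) differed in sign (adjusted p = 0.831, tested as up). Among 15 thymic stroma and endothelium genes, Sparc, Col1a2 and Krt18, of matrix and epithelium, rose by 4.25 ± 0.77, 3.70 ± 0.90 and 2.89 ± 0.43, and 1 fell (5 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.0557). In WT cells Sparc was above background on 2 of 3 arrays and Col1a2 on 1 of 3. Ifng, Ccl4 and Klra1, of NK cells, fell by 3.50 ± 0.86, 2.52 ± 0.61 and 1.52 ± 0.38, the 3 of 33 NK and innate lymphoid genes that fell (5 adjusted over the list alone; median -0.96, adjusted p = 0.140). Cd28 fell by 1.09 ± 0.24, the 1 of 34 pre-TCR and TCR signalling genes called (median -0.09, adjusted p = 0.909).

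The double deletion changed 2001 features (975 rose, 1026 fell, of which 760 and 294 named), against 7470 at an unadjusted p under 0.05, with a median change of all features of -0.14. With slide as a block, which again amounts to leaving out double-deleted DN1, 552 features were called (447 rose, 105 fell), 526 of them among the 2001, and within slide 1, at DN2 and DN3, 363 (333 and 30), 315 of them shared. The changes of the 33 called genes named here were 0.709 to 1.12 times as large with the block, and 18 kept their call, among them Bex1 (9.04), Cdkn2a (8.99), Ncam1, Lin28b, Cdkn1c and Hey1, while Trp53 (-2.53, adjusted p = 0.115), Bmi1, Perp, Phf19, Dnmt3a, Bmf, Bik, Sparc, Col1a2, Ifng, Ccl4, Klra1, Cd28, Cst8 and Rhox2h did not. Within slide 1, 15 of the 33 kept their call, with changes 0.6 to 1.29 times as large. Arsi, Igf1r, Socs2, Tmem88, Slc38a8 and Kcnh6 lost it there alone, and Perp, Bik and Sparc with the block alone. With slide as a random block, at an estimated slide correlation of -0.111, 2200 features were called (1024 rose, 1176 fell). All 33 genes kept their call there. That setting was less strict than the reported fit and is no guard against a slide effect. Normexp background correction called 1643 higher and 8690 lower, with a median of all features of -0.27, and scaling on probes detected on all arrays 779 and 381. With 1 array left out the count ran from 395 (338 rose, 57 fell), without double-deleted DN2, to 1869.

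Ezh2-deleted and p53-deleted cells, all on slide 2, were compared directly to set the 2 deletions against each other on 1 slide. These arrays also differ in Xist and Y-linked transcripts, so the deletions cannot be told apart from a difference in the sex of the cells. Trp53 was at least 39.7-fold higher in Ezh2-deleted cells (3 arrays per genotype, adjusted p = 0.00463), and 3 of 34 p53 target genes rose: Phlda3, an inhibitor of AKT, by 3.15 ± 0.35, Dcxr by 3.18 ± 0.40 and Cdkn1a by 1.43 ± 0.32 (5 adjusted over the list alone; median 0.26, adjusted p = 0.0529). Xist was at least 86.7-fold higher, and the Y-linked Eif2s3y and Ddx3y were at least 82.6-fold and at least 41.5-fold lower. Lbhd2, Mpped2, Rps6ka6 and Mst1r were at least 66.8-, 44.4-, 26.2- and 29.1-fold higher, Mst1r on 2 of 3 arrays. Lrig3, a receptor regulator, rose by 6.08 ± 0.43 and Rab38, a trafficking GTPase, by 5.70 ± 0.78, above background on 1 of 3 and 2 of 3 p53-deleted arrays. Dcxr was above background on 2 of 3 of the latter. Lgals7, a galectin, Sat2, an acetyltransferase, and the developmental factors Foxb1 and Lhx2 were at least 69.2-, 65.8-, 57.0- and 24.6-fold lower. Col1a2, above background on 1 of 3 Ezh2-deleted arrays, fell by 4.94 ± 0.90 and Xaf1, an interferon-induced death factor whose probes disagreed in sign, by 5.24 ± 0.27. Ezh2 did not pass (-0.15 ± 0.39).

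The PRC2 target genes went both ways between the single deletions: 6 of 42 were higher in Ezh2-deleted and 5 in p53-deleted cells (11 and 6 adjusted over the list alone, median 0.29, or 0 at bounds, adjusted p = 0.25). Hoxa7 rose by 3.89 ± 0.36, while Cdkn2a and Cdkn2b, neighbouring cell cycle inhibitors, fell by 4.43 ± 0.62 and 4.05 ± 0.49. Bcl11a, Erg and Mycn, transcription factors of progenitors, rose by 4.22 ± 0.42, 3.34 ± 0.58 and 2.22 ± 0.48, among 29 stem and early progenitor genes (9 adjusted over the list alone; median 0.98, adjusted p = 0.00044, and adjusted p = 0.788 with an estimated correlation). Notch3, Hey1 and Il2ra rose by 2.39 ± 0.48, 2.06 ± 0.43 and 1.92 ± 0.43, among 15 Notch target genes (5 adjusted over the list alone; median 0.79, adjusted p = 0.0376, and adjusted p = 0.652 with an estimated correlation). Cd8b1, Cd4, Cd28 and Cd5 fell by 3.04 ± 0.37, 1.83 ± 0.23, 1.53 ± 0.24 and 1.60 ± 0.32. They were the 4 of 34 pre-TCR and TCR signalling genes called (5 adjusted over the list alone; median -0.20, adjusted p = 0.0546). Bcl11a and Erg were above background on 1 of 3 and Hoxa7 and Hey1 on 2 of 3 p53-deleted arrays, and Cdkn2b and Cd8b1 on 2 of 3 Ezh2-deleted arrays.

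Bcl11b, a factor of T cell commitment, rose by 1.04 ± 0.23 and Id3, an inhibitor of E proteins, fell by 1.44 ± 0.30, and 1 further member of 27 T-lineage transcription factors was called (median -0.10, adjusted p = 0.961). Cd79b and Btk, of B cell receptor signalling, rose by 2.66 ± 0.31 and 3.18 ± 0.68, among 20 B-lineage genes (4 adjusted over the list alone; median 0.83, adjusted p = 0.0092, and adjusted p = 0.825 with an estimated correlation). The list stood at 0.95 in Ezh2-deleted and -2.003 in p53-deleted DN1 cells, but at -2.45 and -2.97 at DN2 and at -3.41 and -3.30 at DN3. Btk was above background on 2 of 3 p53-deleted arrays. Tet1, which oxidises methylated DNA, rose by 1.64 ± 0.21, the 1 of 18 DNA methylation genes called (median 0.30, adjusted p = 0.0669). Cd8b1 and Cd4 were the 2 of 22 double-positive thymocyte genes called (3 adjusted over the list alone; median -0.35, adjusted p = 0.00921, and adjusted p = 0.730 with an estimated correlation), and none of 26 immediate-early and heat-shock genes was (median -1.05, adjusted p = 0.000231, and adjusted p = 0.759 with an estimated correlation). That list stood at 4.87 and 4.55 in Ezh2-deleted and p53-deleted DN1 cells, and at 3.31 and 5.84 at DN2. In total 1060 features differed (602 higher, 458 lower in Ezh2-deleted cells, and 5210 at an unadjusted p under 0.05). With slide as a block the changes were the same, 774 were called and 31 of the 37 called genes named here kept their call, all but Bcl11b, Btk, Cd5, Hey1, Id3 and Mst1r. Within slide 2 alone, where the changes were the same but fewer arrays set the spread, 90 were, and 16 of the 37 kept their call. Cdkn1a, Phlda3, Dcxr, Notch3, Il2ra, Cd4, Cd28 and Cd8b1 were among those that did not. The count ran from 271, without Ezh2-deleted DN2, to 1017 with 1 array left out.

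**Figure D3:**
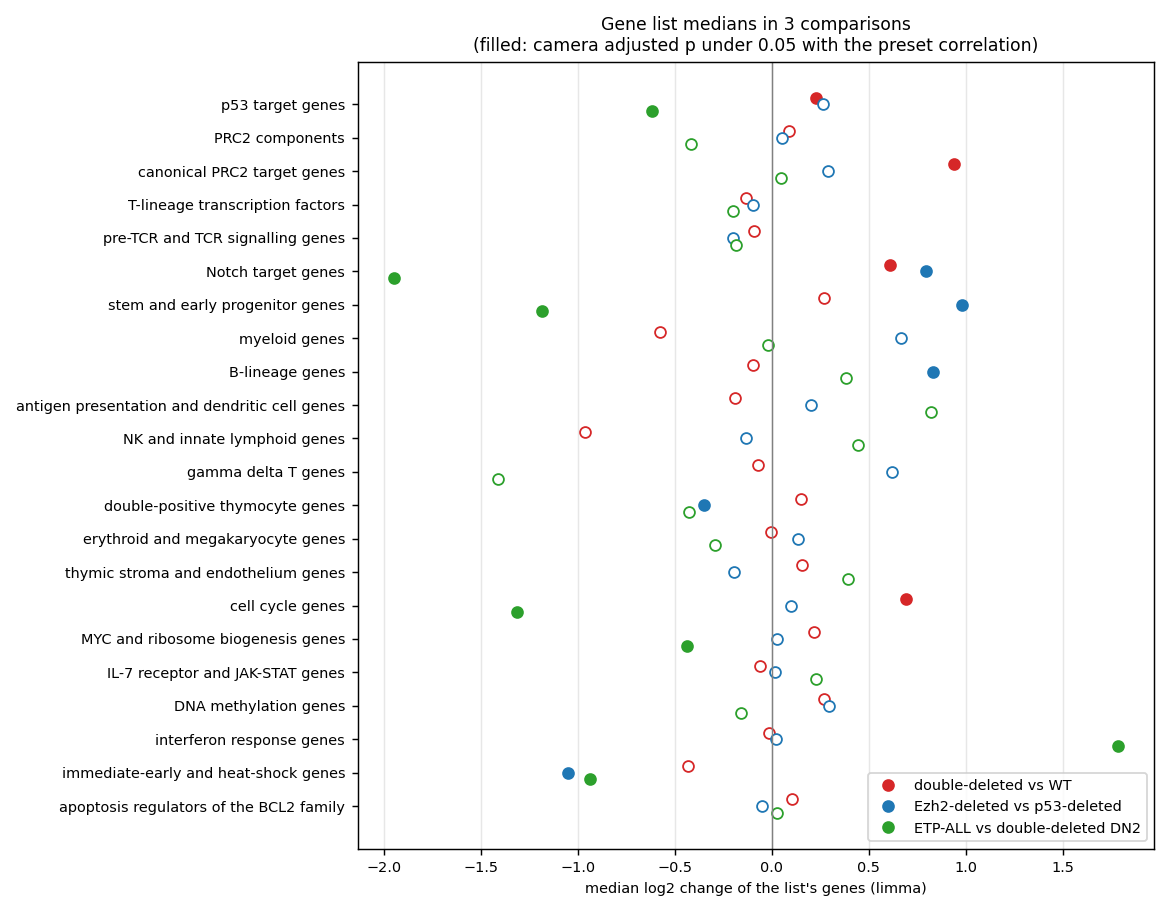
Median log2 change of the 22 gene lists in 3 comparisons, with red for double-deleted against WT, blue for Ezh2-deleted against p53-deleted and green for ETP-ALL against double-deleted DN2; filled points were called by camera with the preset correlation and 0 were called with an estimated one. Interferon response genes have a median of 1.79 in the leukemias and Notch target genes one of -1.95, while PRC2 target genes have one of 0.94 in double-deleted against WT cells.

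The single deletions against WT, double-deleted against p53-deleted cells and the interaction lie between slides 1 or 3 and the dim slide 2, so genotype and slide cannot be told apart in them. In Ezh2-deleted against WT cells, Bex4 and Fbln1, a matrix protein, were at least 137-fold and at least 39.6-fold higher, Bex1 rose by 6.48 ± 0.52, Cdkn2a by 5.96 ± 0.62 and Yap1, a Hippo pathway effector, by 5.95 ± 0.52. Cdkn2a and Yap1 were above background on 1 of 3 WT arrays. In p53-deleted against WT cells, Cdkn2a rose by 10.39 ± 0.62 (adjusted p = 6.37e-06), Cnnm1, Lgals7, Fbln1 and Bex4 were at least 92.1-, 67.9-, 58.8- and 54.6-fold higher, Pdlim4 rose by 6.22 ± 0.75 and Trp53 was at least 31.5-fold lower. The mitochondrial glutamate carrier Slc25a22 was at least 50.3-fold lower in Ezh2-deleted and at least 52.3-fold lower in p53-deleted cells. The phosphatase Ppp5c, above background on 1 of 3 Ezh2-deleted arrays, fell by 6.50 ± 0.46 in the former and was at least 119-fold lower in the latter. Npm3, a histone chaperone, was at least 53-fold and Eif2s3y at least 145-fold lower in Ezh2-deleted cells, and Hes1, a Notch effector, at least 90.1-fold lower in p53-deleted cells. Of 28 interferon response genes, 22 rose and 1 fell in Ezh2-deleted cells (24 and 1 adjusted over the list alone; median 1.36, adjusted p = 1.03e-07, and adjusted p = 0.589 with an estimated correlation) and 24 rose in p53-deleted cells (24 adjusted over the list alone; median 1.15, adjusted p = 1.31e-08, and adjusted p = 0.589 with an estimated correlation). Examples are Isg15 (1.92 ± 0.26) in the former and Irf7 (2.02 ± 0.31) in the latter. The antigen presentation and dendritic cell genes had medians of 0.86 and 0.79 in the 2 comparisons, without a call (adjusted p = 0.296 and 0.554). The NK and innate lymphoid genes had medians of 0.56 in the former and 0.805 in the latter. Against WT of the same stage the antigen presentation list reached 1.58 in Ezh2-deleted DN1 and 2.42 in p53-deleted DN2 cells and stood at -0.33 in p53-deleted DN1 cells, where the interferon list stood at 1.11. Xaf1 fell by 3.20 ± 0.27 in Ezh2-deleted cells, with probes that disagreed, and rose by 2.04 ± 0.27 in p53-deleted cells.

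Cd3e, a signalling chain of the T cell receptor, rose by 1.75 ± 0.29 and 1.35 ± 0.29 in Ezh2-deleted and p53-deleted cells, and Bcl11b by 1.03 ± 0.23 in the former. In Ezh2-deleted cells 8 of 27 T-lineage transcription factors rose (7 adjusted over the list alone, median 0.55, adjusted p = 0.0452, and adjusted p = 0.825 with an estimated correlation), though under normexp camera ranked that list on the lower side (median 0.28, adjusted p = 0.793, against a median of all features of 0.35). IL-7 receptor and JAK-STAT genes were higher in Ezh2-deleted cells (5 of 27, median 0.57, adjusted p = 0.0236, and adjusted p = 0.825 with an estimated correlation) and in p53-deleted cells (7 of 27, median 0.59, adjusted p = 0.039, and adjusted p = 0.855 with an estimated correlation). In p53-deleted cells 12 of 34 pre-TCR and TCR signalling genes rose and 2 fell (14 and 2 adjusted over the list alone; median 0.89, adjusted p = 0.00431, and adjusted p = 0.788 with an estimated correlation). The PRC2 target genes as a group moved in neither: 8 of 42 rose and 9 fell in Ezh2-deleted cells (median 0.11, or 0 at bounds, adjusted p = 0.795), and 8 rose and 11 fell in p53-deleted cells (median -0.36, or 0 at bounds, adjusted p = 0.629). Cdkn1a stood at -0.93 ± 0.32 in p53-deleted cells and just missed the threshold (adjusted p = 0.0502), and Ezh2 did not pass in either comparison (-0.24 ± 0.39 and -0.09 ± 0.39), nor Trp53 in Ezh2-deleted cells (0.33 ± 0.70). Ezh2-deleted cells differed from WT in 9223 features (4220 higher, 5003 lower, and 12218 at an unadjusted p under 0.05, median 0.10), and p53-deleted cells in 9691 (4143 and 5548, and 12511, median 0.05). Normexp gave 9946 and 3565 for the former, with a median of all features of 0.35, and 8147 and 3828 for the latter, with one of 0.27. With slide as a random block the counts were 12098 and 12461, at an estimated slide correlation of -0.111. Such a block removes no slide effect where genotypes lie wholly between slides, so these higher counts do not tell slide from genotype.

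Against p53-deleted cells, double-deleted cells had Lin28b at least 13.5-fold, Hoxc4 at least 14.8-fold and Mpped2 at least 47.5-fold higher, and Hoxa7, above background on 2 of 3 p53-deleted arrays, rose by 4.94 ± 0.36. Of 42 PRC2 target genes 23 rose and 2 fell (25 and 4 adjusted over the list alone; median 1.36, or 0.69 at bounds, adjusted p = 4.65e-06, and adjusted p = 0.616 with an estimated correlation). Of the interferon response genes 19 fell (20 adjusted over the list alone; median -1.17, adjusted p = 1.71e-07, and adjusted p = 0.589 with an estimated correlation). The antigen presentation and dendritic cell genes had a median of -1.21, without a call (adjusted p = 0.397). Of the pre-TCR and TCR signalling genes 14 fell by either adjustment (median -0.84, adjusted p = 0.000944, and adjusted p = 0.730 with an estimated correlation), such as Cd5 by 2.32 ± 0.32, Cd28 by 1.52 ± 0.24 and Cd3e by 1.30 ± 0.29. Runx1 fell by 1.02 ± 0.30 and Il2ra rose by 1.38 ± 0.43, while Cdkn2a (-1.27 ± 0.62) and Ezh2 (0.47 ± 0.39) did not pass. Ppp5c and Slc25a22 were at least 91.8-fold and at least 39.2-fold higher. Trp53 was at least 3.34-fold higher, though not under normexp (-0.19, adjusted p = 0.571). At DN1 its signal was no higher, at -4.05 against -3.7 in p53-deleted cells. It was not above background in the latter, so no difference is given. Stem and early progenitor genes were higher (8 rose and 1 fell of 29, median 0.85, adjusted p = 0.0247, and adjusted p = 0.885 with an estimated correlation). T-lineage transcription factors were lower (1 rose and 8 fell of 27, median -0.44, adjusted p = 0.0452, and adjusted p = 0.825 with an estimated correlation), which normexp turned around relative to other genes (median -0.06, adjusted p = 0.414). NK and innate lymphoid genes were lower (1 rose and 8 fell of 33, median -1.15, adjusted p = 0.0466, and adjusted p = 0.919 with an estimated correlation). The filter on all arrays turned this around only relative to other genes (median -0.06, against -0.21 for all features, adjusted p = 0.67). In this comparison 8451 features were called (4323 higher, 4128 lower, and 11803 at an unadjusted p under 0.05, median -0.12), and normexp called 3779 and 12342, with a median of -0.44. The random block, at the same slide correlation of -0.111, called 10575 and likewise removes no slide effect.

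The interaction, in which the double deletion is set against the sum of the single ones, was called for 12149 features (5762 above and 6387 below the sum, and 14393 at an unadjusted p under 0.05, median -0.24). Normexp gave 4271 and 13775, with a median of -0.79. The random block gave 16934, again at a slide correlation of -0.111 and without removing a slide effect. Ppp5c and Slc25a22 were called above the sum and Xist and Fbln1 below it, each not above background in at least 1 genotype, so no size is given. Cdkn2a, raised in both single deletions and above background on 1 of 3 WT arrays, stood at -7.23 ± 0.87, Cd3e at -3.06 ± 0.41 and Runx1 at -1.53 ± 0.43. Ezh2 (0.71 ± 0.56) did not pass. Nor did Trp53, above the sum but not above background in p53-deleted cells, so no size is given. Of 42 PRC2 target genes 21 were above and 6 below the sum (22 and 8 adjusted over the list alone; median 2.24, adjusted p = 0.00658, and adjusted p = 0.730 with an estimated correlation), a direction that turned under normexp (-0.83, adjusted p = 0.38) and under the filter on all arrays (-1.09, adjusted p = 0.67). Of 28 interferon response genes 1 was above and 24 below (the same counts adjusted over the list alone; median -2.54, adjusted p = 4.11e-08, and adjusted p = 0.589 with an estimated correlation). T-lineage transcription factors (10 of 27 below, median -0.93, adjusted p = 0.0247, and adjusted p = 0.799 with an estimated correlation) and pre-TCR and TCR signalling genes (3 above and 16 below of 34, median -1.41, adjusted p = 0.0092, and adjusted p = 0.825 with an estimated correlation) were below the sum, though not relative to all features under normexp (-0.20 and -0.53, adjusted p = 0.485 and 0.909).

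The leukemias were compared with non-leukemic double-deleted DN2 cells to find what distinguishes overt disease. Pitx1, a homeobox gene and PRC2 target, and the membrane protein gene Shisa3 were at least 56.6-fold and at least 76.5-fold higher in the mean of both leukemias (2 arrays, adjusted p = 0.00027 each). The bounds of this comparison are set against the double-deleted DN2 array. Each p is set against the additive estimate and takes its spread mostly from non-leukemic arrays. Pcsk1, a prohormone protease, and Il15, the cytokine of NK and memory T cells, were at least 94.0-fold and at least 79.2-fold higher. Igsf23, Csprs, Tafa3 and Gtsf1, the last a factor of transposon silencing, were at least 59.4-, 57.6-, 52.9- and 52.0-fold higher. Klk8, a protease, Mpped2, Khdrbs3, an RNA-binding protein, Fabp4, a fatty acid carrier, and Clec4e, a receptor of myeloid cells, were at least 48.1-, 47.7-, 45.4-, 44.8- and 36.3-fold lower. Mdga1 fell by 7.67 ± 1.63 and Ptcra, the pre-T cell receptor alpha chain, by 6.29 ± 1.22, each above background in 1 of 2 leukemias. Ezh2 (-1.12 ± 0.50) and Trp53 (-2.44 ± 0.94) did not pass, nor did Cdkn2a (1.92 ± 0.73), Lef1 (-3.19 ± 1.24) or Runx1 (-0.97 ± 0.35).

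Interferon response genes rose together in the leukemias. Ifi44, Gbp2, Rsad2 and Oasl1 rose by 3.03 ± 0.36, 3.94 ± 0.48, 2.48 ± 0.33 and 2.03 ± 0.27, and 15 of 28 rose over all genes and 27 adjusted over the list alone (median 1.79, camera adjusted p = 3.46e-24, and adjusted p = 0.238 with an estimated correlation). The median differences from the double-deleted DN2 array were 2.02 and 2.12. Beside this, 20 antigen presentation and dendritic cell genes had median differences of 0.93 and 1.30 from that array, with none called (median 0.82, adjusted p = 0.0834). Irf8, a factor of dendritic cells and monocytes, rose by 2.50 ± 0.55 and Tyrobp, a signalling adaptor of myeloid and NK cells, fell by 4.32 ± 0.91, above background in 1 of 2 leukemias. Of 32 myeloid genes 1 rose and 2 fell (median -0.02, adjusted p = 0.207). Epcam, an epithelial adhesion molecule, rose by 3.29 ± 0.46, the 1 of 15 thymic stroma and endothelium genes called (3 adjusted over the list alone; median 0.39, adjusted p = 0.0632).

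Notch target and stem cell genes were lower in the leukemias. Hey1 fell by 5.28 ± 0.80 and Hes5, another Notch effector above background in 1 of 2 leukemias, by 3.90 ± 0.46, and with Ptcra they were the 3 of 15 Notch target genes that fell (7 adjusted over the list alone; median -1.95, adjusted p = 1.33e-05, and adjusted p = 0.589 with an estimated correlation). Bcl11a and Gfi1b were at least 19.4-fold and at least 9.84-fold lower, and Erg was lower too, all 3 not above background in either leukemia. Ly6a, the stem cell antigen Sca-1, itself induced by interferon, rose by 4.77 ± 0.31 (adjusted p = 0.00027). Of 29 stem and early progenitor genes 1 rose and 8 fell adjusted over the list alone (median -1.19, or -0.97 at bounds, adjusted p = 0.000467, and adjusted p = 0.730 with an estimated correlation). No cell cycle gene was called (median -1.32 over 39, adjusted p = 1.24e-08, and adjusted p = 0.825 with an estimated correlation), with medians of -2.23 and -0.41 in the 2 leukemias, and no MYC and ribosome biogenesis gene was (median -0.44, adjusted p = 0.0220, and adjusted p = 0.955 with an estimated correlation). Hsph1, a chaperone, fell by 2.59 ± 0.36 and Hspa1a was at least 49.3-fold lower, the 2 of 26 immediate-early and heat-shock genes called (4 adjusted over the list alone; median -0.94, adjusted p = 0.000403, and adjusted p = 0.730 with an estimated correlation). That list went opposite ways in the 2 leukemias, at 0.21 and -2.35 from the double-deleted DN2 array. Pmaip1, the p53-induced death gene Noxa, fell by 2.67 ± 0.44, the 1 of 34 p53 target genes called (2 adjusted over the list alone; median -0.62, adjusted p = 0.0092, and adjusted p = 0.616 with an estimated correlation).

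The PRC2 target genes showed no common direction in the leukemias: 4 of 42 rose over all genes, and 6 rose and 4 fell adjusted over the list alone (median 0.05, adjusted p = 0.489). Hoxc6 and Hoxc9 rose by 4.07 ± 0.64 and 3.73 ± 0.79, and Hoxb3 was at least 3.74-fold higher. Plcg1, a phospholipase of T cell receptor signalling, fell by 1.80 ± 0.26 and Cd8a was at least 3.71-fold lower, and Socs1, an inhibitor of cytokine signals above background in 1 of 2 leukemias, fell by 5.83 ± 1.18. In all, 654 features differed (390 higher, 264 lower, and 4858 at an unadjusted p under 0.05, median -0.02). Without the arrays of slide 2 the count was 79, and 10 of the 37 called genes named here kept their call, with changes 0.901 to 1.16 times as large. Against the 4 non-leukemic DN2 arrays alone the count was 3, against the 3 non-leukemic double-deleted arrays 131, and without the double-deleted DN2 array 99. Both leukemias lay on a slide of their own, so slide and disease cannot be told apart.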

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

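The tests of genes shared by both single deletions and the test of RNA from other cells were chosen after the results they concern were seen. The other tests in this part were written beforehand.

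Among 76 groups of 4 samples or more checked for a single distant value, 5 held one, and about 1 in 20 is what chance gives. From DN1 to DN2 the canonical PRC2 target genes had a median change of 0.59 in Ezh2-deleted cells, against -0.10 to 0.01 in the other genotypes. Gata3 and Hoxa9 changed by 0.57 and 0.98 in p53-deleted cells over the same step, against -1.08 to -0.86 and -0.32 to -0.15 in the others. From DN2 to DN3 the thymic stroma and endothelium genes had a median change of 0.31 in p53-deleted cells, against -0.23 to -0.14, and the interferon response genes one of 0.16 in double-deleted cells, against -0.33 to -0.26. None of these single-array differences was tested further.

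A difference between groups was found for 12149 features whose change on losing both genes was not the sum of the single changes. Both single deletions lie on slide 2, so this was weighed through the 6539 features called the same way in both against WT, 2413 up and 4126 down, where independent calls would give 646 and 1025, and 52 were called in opposite directions. In simulated data the shared WT arrays alone gave a correlation of 0.5 and 0 such features, against 0.81 in the real data. The simulated noise was independent for each gene and array. The simulation therefore cannot tell what an error common to many genes on the WT arrays or on a slide would give. Within slide 1 the double-deleted minus WT shift of these features was 0.40, or 24.4% of their shift of 1.65 in the single deletions (13.2% for those that rose, 24.8% for those that fell). Added effects of losing either gene would need 100% or more, if the slide 2 arrays measure the deletions alone. The value of 24.4% is lower. However, the features were chosen by their calls in the single deletions, which can enlarge the shift of 1.65. Slide 1 also holds no double-deleted DN1 array, while the single deletions were taken over all stages. A share under 100% can thus arise in part from the choice of features and stages. The test therefore does not decide against added effects, which stay open. In writing that test the share was first taken over risen genes and then over the higher of both directions. The share over all was then settled on, and each of these shares was under 100%.

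The slide and scan session of the single-deleted arrays remain open as a cause, since 24.4% lies between the bounds of under 10% and at least 50% set for that test, and slide and genotype cannot be told apart. Weak signal that pushes dim probes to the floor also stays open: the median WT level of the fallen features, -0.28, stood at the 54.7th percentile of tested features, whose median was -0.74. An effect that single deletions share and the double deletion lacks may also contribute and was not tested.

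The higher interferon response genes in the leukemias, by 2.02 and 2.12 over the double-deleted DN2 array, were weighed against 2 technical causes. RNA from dendritic or other antigen-presenting cells may contribute: of the lists for 6 other cell types the antigen presentation and dendritic cell genes rose most, with medians of 0.93 and 1.30. NK and innate lymphoid genes stood at 0.35 and 1.01, thymic stroma and endothelium genes at 0.56 and 0.03 and B-lineage genes at -0.17 and 0.58. The abundant members moved apart, with Cd74 at 1.91 and 3.67, H2-Eb1 at 1.32 and 3.76, Siglech at 0.66 and 0.65 and Cst3 at -0.52 and -0.17. That list shares 1 gene with the interferon list, and 16 of its 20 genes were above background in double-deleted DN2 cells. The sort steps named are the CD4-CD8- selection and the DN2 gate on CD44 and CD25. How far these remove dendritic or other antigen-presenting cells was not tested. The features shifted on slide 2 moved in the leukemias by 0.10 and 0.17, at most 10.1% of that shift, just above the bound of 10% under which a like array shift would have been excluded.

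Both leukemias share a slide of their own, so that slide cannot be told apart from disease as a source of the interferon difference of 2.02 and 2.12. An interferon response of the leukemic cells themselves stays open beside RNA from other cells (0.93) and was not tested.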

How the results depend on the processing

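The scaling on probes detected on all arrays, the filter on detection throughout 1 group, and the fits within or without a slide, except double-deleted against WT on slide 1, were tests chosen after the data were seen. No paired analysis was possible by replicate number, because the labels of the 12 non-leukemic arrays carry no replicate numbers, though the fit itself is blocked and sets stages against each other within genotypes and genotypes within stages. Of 112 values for 10 counts, 86 stayed within 1.5 times the reported count and 26 did not. Of 698 values for 56 called lists, 549 kept direction and call, 142 lost the call and 7 changed direction relative to other genes. Of 2372 values for 215 named gene results, 1980 kept both, 374 lost and 11 gained the call and 7 changed sign. The cause was not tested except where fewer arrays or probes entered.

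For DN2 vs DN1, in place of 373, the filter on all arrays gave 153, which tests fewer probes, the trended and robust prior 627, the filter on 1 group 578 and slide 2 alone 5, with fewer arrays. For DN3 vs DN2, in place of 6, these gave 25, 24, 36 and 0, slide 1 alone gave 0 and leaving slide 2 out 1. By limma 1560 and 1504 features had an unadjusted p under 0.05 within slides 1 and 2. For double-deleted vs WT, in place of 2001, normexp gave 10333, scaling on detected probes 1160, the slide block, which amounts to leaving out double-deleted DN1, 552, DN2 and DN3 of slide 1 gave 363 and leaving out slide 2 gave 627. For Ezh2-deleted vs p53-deleted, in place of 1060, normexp gave 354, the filter on all arrays 559 and slide 2 alone 90. Normexp gave 16121 for double-deleted vs p53-deleted in place of 8451. For ETP-ALL vs double-deleted DN2, in place of 654, normexp gave 1479, the filter on all arrays 398, leaving out slide 2 gave 79, the 4 non-leukemic DN2 arrays as reference 3 and the 3 double-deleted arrays 131. Gene list tests called 56 lists, 32 under the filter on all arrays and 0 with an estimated correlation.

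Normexp turned T-lineage transcription factors in Ezh2-deleted vs WT (0.283), double-deleted vs p53-deleted (-0.057) and the Ezh2 by p53 interaction (-0.203) around relative to other genes. In that interaction it also turned canonical PRC2 target genes (-0.828) and pre-TCR and TCR signalling genes (-0.533), and the filter on all arrays turned PRC2 target genes (-1.09). That filter turned NK and innate lymphoid genes in double-deleted vs p53-deleted around relative to other genes, with a median still negative (-0.057). Trp53 changed sign in DN2 vs DN1 with the slide block (-0.159) and within slide 2 (-0.425), and under normexp in double-deleted vs p53-deleted (-0.192) and the interaction (-0.276). Ezh2 changed sign in double-deleted vs WT within slide 1 (-0.148) and in DN3 vs DN2 within slide 1 (-0.022) and without slide 2 (-0.022).

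Leaving out 1 array moved 27 of 61 counts by over 1.5 times. A group left with fewer arrays takes its spread from all. DN2 vs DN1 ran from 141 to 2418: 168 without WT DN1, 155 without WT DN2, 185 without Ezh2-deleted DN1, 141 without Ezh2-deleted DN2, 2418 without p53-deleted DN1, 1790 without p53-deleted DN2 and 212 without double-deleted DN2. DN3 vs DN2 ran from 2 to 10: 2 without WT DN2, WT DN3 or Ezh2-deleted DN2, 3 without Ezh2-deleted DN3, p53-deleted DN3 or double-deleted DN2, and 10 without double-deleted DN3. Ezh2-deleted vs WT ran from 6085, without WT DN2, to 9085, and p53-deleted vs WT from 6755 to 8833. Double-deleted vs WT ran from 395 to 1869: 848 without WT DN1, 585 without WT DN2, 552 without double-deleted DN1, 395 without double-deleted DN2 and 690 without double-deleted DN3. Ezh2-deleted vs p53-deleted ran from 271 to 1017: 683, 271 and 378 without Ezh2-deleted DN1, DN2 and DN3, and 436 without p53-deleted DN3. Double-deleted vs p53-deleted ran from 4766, without double-deleted DN2, to 7680, with 5260 without double-deleted DN3. The interaction ran from 9762 to 11838, and ETP-ALL vs double-deleted DN2 from 99, without double-deleted DN2, to 834.

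With 1 array left out, 962 of 1314 values of named genes kept direction and call, 337 lost and 4 gained the call and 11, all of the targeted genes, changed sign. For Ezh2 the ranges that cross 0 were -0.102 to 0.678 in double-deleted vs WT, -0.722 to 0.058 in Ezh2-deleted vs WT, -0.57 to 0.244 in p53-deleted vs WT, -0.485 to 0.212 in Ezh2-deleted vs p53-deleted and -0.168 to 0.262 in DN3 vs DN2. For Trp53 they were -0.159 to 1.115 in DN2 vs DN1, -0.068 to 0.807 in DN3 vs DN2 and -0.013 to 0.585 in Ezh2-deleted vs WT. None of these was called in the reported fit. Signal over background limits all fold changes of genes at the floor.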

Other observations

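The random sets below were chosen as a test after the result they concern was seen, and the other tests of this part were written beforehand.

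Of the features raised by at least 2 on the log2 scale in double-deleted DN1 and DN3 cells, 461 in number and 375 of them named genes, the median over WT DN2 was 3.57 in double-deleted DN2 cells and 3.04 and 2.78 in the leukemias. The lower leukemic median was 78.1% of that in double-deleted DN2 cells, so the leukemias largely kept the rise of these features. The features were chosen without regard to the single deletions, so the value does not tell the double deletion from the loss of either gene. In the leukemias 75.7% and 73.8% of these features stood at least 1 above WT DN2, against 15.7% and 13.3% of all tested features. Of 1000 random sets matched on the WT DN2 level the highest medians were 0.64 and 0.31. These sets did not have to be detected or raised in double-deleted cells, so they show only what unselected features give. The leukemias come from other mice on another slide, but all arrays are set against the same WT DN2 array. A state that leukemic cells keep from before leukemia therefore remains a hypothesis.

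A return of the leukemias to the DN1 pattern was tested by the correlation, across genes, of their difference from the double-deleted DN2 array with WT DN1 minus WT DN2. It was 0.26 and 0.19, the lower at 0.192, where over 0.2 in both was the bound for such a return and under 0.05 the bound against it, so the question stays open. Genes are not independent replicates, and each difference rests on single arrays.

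Other splits of the same arrays were compared with the real ones. For DN2 against DN1, 1 of 35 splits, the real one, gave 373 features, and the highest other gave 46. For DN3 against DN2, 2 of 35 splits gave 6 or more, the highest 8, so chance cannot be excluded. That highest split groups the DN2 and DN3 arrays of WT and Ezh2-deleted cells. With genotype in the fit, it sets their change from DN1 against that in the other genotypes. These splits also exchange arrays across genotypes, and exchanges within genotypes alone make 8 splits, too few for a share under 0.05. Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. In these the real split, 1 of 10, gave 9223 features for Ezh2-deleted and 9691 for p53-deleted against WT, 2001 for double-deleted against WT, 1060 for Ezh2-deleted against p53-deleted and 8451 for double-deleted against p53-deleted, and the highest other gave 0 each time. For the interaction 1 of 100 splits gave 12149, and the highest other gave 10343. That split keeps the 6 single-deleted arrays, all on slide 2, against the other 6, as the real one does, so it does not tell slide from genotype. No value within a slide can be had for it.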
